A study of Homo sapiens with 4 samples.

How the data were processed

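RNA from A549 lung cancer cells was measured on Illumina HumanHT-12 BeadChips, 1 array of cells given a non-targeting siRNA and 3 arrays of cells given siRNAs against EPEL. Per the labels, between 150000 and 200000 cells were plated per well and transfected with 50 nM siRNA by a cationic lipid reagent. The medium was changed after 4 h, and the knockdown was measured by RT-qPCR at 48 h, a result not used here. Per the labels, RNA was isolated with a column kit and amplified to biotin-labelled cRNA. The intensities that the authors deposited are mean bead signals per probe, exported from BeadStudio per the submitters' processing notes, with no version given. These raw intensities were on a linear scale, all above 0, and neither background-subtracted nor normalized between arrays. Each intensity comes with a detection p-value, per the file headers, in steps of 1 in 770, the share of negative control beads at least as bright. A further table holds the authors' processed intensities of the same arrays. From its values it is linear and background-subtracted (12911 to 12941 values below 0 per array). Its medians were nearly alike, at 10.8, 10.8, 10.8 and 10.7 for the control and siRNAs 1, 2 and 3. It therefore looks normalized between arrays, but the values do not settle by which method. The processed table ranked the probes of each array exactly as the raw signal did (Spearman correlation 1), and it served as an alternative. How the authors set its background is not given in the sources used here.

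Groups came from the labels, which name the siRNA of each sample and number the siEPEL samples 1 to 3. The median raw signal per array was 68.3, 67.1, 65.9 and 65.9, and the mean 404, 394, 381 and 387, for the control and siRNAs 1, 2 and 3. The number of arrays limits the precision. Raw intensities were processed with neqc of limma 3.58.1 in R 4.3.3: normexp background correction from the detection p-values, quantile normalization, an offset of 16 and log2. Because of the offset, fold changes of dim probes are understated. Probes with a detection p under 0.01 on at least 1 array were tested, 18200 in all. Gene names came from the annotation of the array platform, updated by gene identifier through a RefSeq table of assembly GRCh38.p14, which changed 0 symbols. Of the 47228 probes, 30113 had 1 gene, 8 had several and 17107 were unnamed here. The tested probes covered 10921 genes, each represented by its brightest tested probe. No coordinates are given, since the files name no genome build.

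siEPEL was compared with control by lmFit and eBayes of limma, 2-sided, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The fit had 2 residual degrees of freedom, among the 3 siEPEL arrays, and 6.83 from the prior. The 18 gene lists, drawn from textbook knowledge before the data were examined, were tested with camera at a preset correlation of 0.01, adjusted over the lists, with fry as a second test. Fry asks whether the genes of a list move, on balance, one way, and camera whether they move relative to other genes. A list value per siRNA is the median log2 ratio of its measured genes to the control array, and 3 genes stand in more than 1 list. A count of probes at least 1.5-fold from the control with all 3 siRNAs, and the correlations between siRNAs, were set beside 200 simulations of unchanged arrays that share 1 control. Where a probe was not detected on any array of a group, the fold is a bound: the mean of the other group against, per array, the higher of the dimmest detected signal and the probe's own. Such a probe passed the detection filter only through the other group, which by itself favours a difference. Named genes followed a fixed rule. They are E2F1 to E2F8, the 12 highest and 12 lowest genes on the same side with all 3 siRNAs, and the 2 members of each list furthest from the control (up to 4 had any passed). With 0 genes past the threshold, the highest and lowest were taken by the smallest of their 3 ratios. Further list members in the text were chosen after their values were seen: RRM2, CCNA2, MCM6, MCM7, PCNA, MKI67, BAX, ISG15 and GAPDH. Of the 65 genes named by the rule, 12 had several tested probes and 4 had probes of opposite sign.

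The tests were tested on simulated data in 20 runs of 18200 probes with 200 changed. On average 181 probes were called, 13.3 of them falsely. Camera with the preset correlation called 95% of lists shifted by -0.22 and 0.294% of unshifted lists when genes were independent. With residuals correlated at 0.3 it called 70% of shifted and 42.4% of unshifted lists, and the estimated correlation called 0% of shifted lists in either case. Alternatives chosen before the data were examined were: no background correction, median scaling, cyclic loess, the authors' processed values, an offset of 50, other detection filters, an intensity trend with or without a robust prior, the mean of a gene's probes, other thresholds and folds, an estimated correlation, fry, and leaving out each siEPEL array. The target's own level was left out because no probe was named for it.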

Results

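Gene expression was measured in A549 cells, a human lung adenocarcinoma line, after transfection with siRNAs against the long noncoding RNA EPEL or with a non-targeting siRNA. EPEL is described as an RNA linked to E2F transcription factors and cell proliferation, so the comparison asks which transcripts differ once it is knocked down. There were 4 arrays: 1 of control cells and 3 of siEPEL cells, each with a different siRNA at 50 nM. The siEPEL replicates 1, 2 and 3 are therefore named here siRNA 1, siRNA 2 and siRNA 3. Each BeadChip carried 47228 probes, with a mean raw signal of 404 on the control array and 394, 381 and 387 with siRNAs 1, 2 and 3. Between 16520 probes (35.0%, control) and 17106 probes (36.2%, siRNA 3) were detected above the negative control beads. The labels do not say that the samples came from separately grown cultures. The p-values of single probes therefore measure only the spread between these samples. Because each siEPEL sample received its own siRNA, that spread holds differences between siRNAs and between transfections besides technical ones. Camera at the preset correlation sets a list against the other genes, which are not independent replicates, so its p-values rest on the spread across genes. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.22.

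The level of EPEL itself was not analysed here, because 0 of the 47228 probes carried its name or its older designation in the probe annotation. How strongly each siRNA lowered its target is therefore not known from these arrays, and the order of the siRNAs below cannot be set against the knockdown.

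No single gene passed the test between siEPEL and control cells, while several groups of genes lay to one side of the control array. Genes of DNA replication, mitosis and the G1/S transition lay lower, with mean list medians of -0.22, -0.21 and -0.21 on the log2 scale. Genes induced by p53 and by interferon lay higher, at 0.23 and 0.20. With limma camera the adjusted p of these 5 lists lay between 1.23e-08 and 0.000214, and all lost the call with an estimated correlation (adjusted p = 0.709). Each shift was largest with siRNA 1 or siRNA 2. With siRNA 1 alone set against the remaining arrays, control included, camera gave all 5 lists the same directions. The control is 1 of those remaining arrays, so a deviation of the control alone would give the same directions. That comparison therefore cannot clear the control array. With siRNA 2 alone the mitosis and G1/S lists turned upward, and with siRNA 3 alone all 5 directions were reversed. Of 18200 probes tested with limma, 0 were higher and 0 were lower at an adjusted p under 0.05, and the smallest adjusted p was 1.00. At an unadjusted p under 0.05 there were 382 probes, 211 higher and 171 lower, against 910 expected by chance. The lone control array was assumed to vary like the siEPEL arrays, whose spread also holds any difference between the siRNAs. In simulations of this comparison with 200 changed probes among 18200, the same test recovered 68.1% of 2-fold and 99.95% of 4-fold changes. The simulations took each probe's spread after moderation by eBayes as its true spread, so these shares may be too high. They do not show that 2-fold changes are absent here.

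Among genes that lay on the same side of the control with all 3 siRNAs, each taken by its brightest probe, the widest differences were those of SUCNR1, a receptor for succinate, and of several genes near the detection limit. None passed the threshold, and they were taken by the smallest of their 3 ratios. SUCNR1 was 1.58-fold, 1.90-fold and 3.27-fold the control with siRNAs 1, 2 and 3, a log2 fold change of 1.10 ± 0.36 (SE), while its dimmer second probe gave 0.37 ± 0.31. On the control array SUCNR1 too lay near the detection limit, at a log2 level of 5.89 against a dimmest detected signal of 5.62. IFFO1 had a log2 fold change of 0.76 ± 0.21, PGAP6 of 0.72 ± 0.20, RNF24 of 0.67 ± 0.20 and CDC42SE2 of 0.64 ± 0.20. A second CDC42SE2 probe gave 0.54 ± 0.20. The other genes on the high side were not detected on the control array, so their folds are lower bounds against the dimmest detected signal there. They passed the detection filter only through siEPEL arrays, which by itself favours a higher siEPEL side. EPHA4, an ephrin receptor, was at least 1.65-fold higher, CUL7, a scaffold of ubiquitin ligases, at least 1.53-fold and MT1E, a metallothionein, at least 1.53-fold. For TMEM182 the bound was at least 1.38-fold, for SDCCAG8 at least 1.3-fold and for KCNMB2, a potassium channel subunit, at least 1.05-fold. TMEM140 was detected on 2 of the 3 siEPEL arrays and not on the control array, and no bound above 1 could be given.

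On the low side, the best measured genes were TMEM19 and SF3B3, a subunit of the splicing factor that recognises the branch point. TMEM19 stood at 0.556-fold, 0.576-fold and 0.655-fold the control, a log2 fold change of -0.75 ± 0.21, and its dimmer second probe gave -0.25 ± 0.34. SF3B3 was at 0.661-fold, 0.596-fold and 0.617-fold, a log2 fold change of -0.68 ± 0.20. SMCHD1, a chromatin protein of gene silencing, had a log2 fold change of -0.77 ± 0.24 and was detected on 2 siEPEL arrays. TENM3-AS1 (-0.87 ± 0.25) and the transcription factor gene ATOH8 (-0.73 ± 0.21) were each detected on 1 siEPEL array. Their siEPEL levels were near background, so these values are not folds. The remaining genes were detected on the control array and on 0 siEPEL arrays. They passed the detection filter only through the control array, which by itself favours a lower siEPEL side. LOC101927531 was at least 1.45-fold lower, ACBD7 at least 1.40-fold and RTN4RL1 at least 1.22-fold. For AMER2 the bound was at least 1.2-fold and for CDHR4 at least 1.14-fold. The small nucleolar RNAs SNORA73A and SNORA68 were at least 1.33-fold and 1.27-fold lower.

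**Figure D1:**
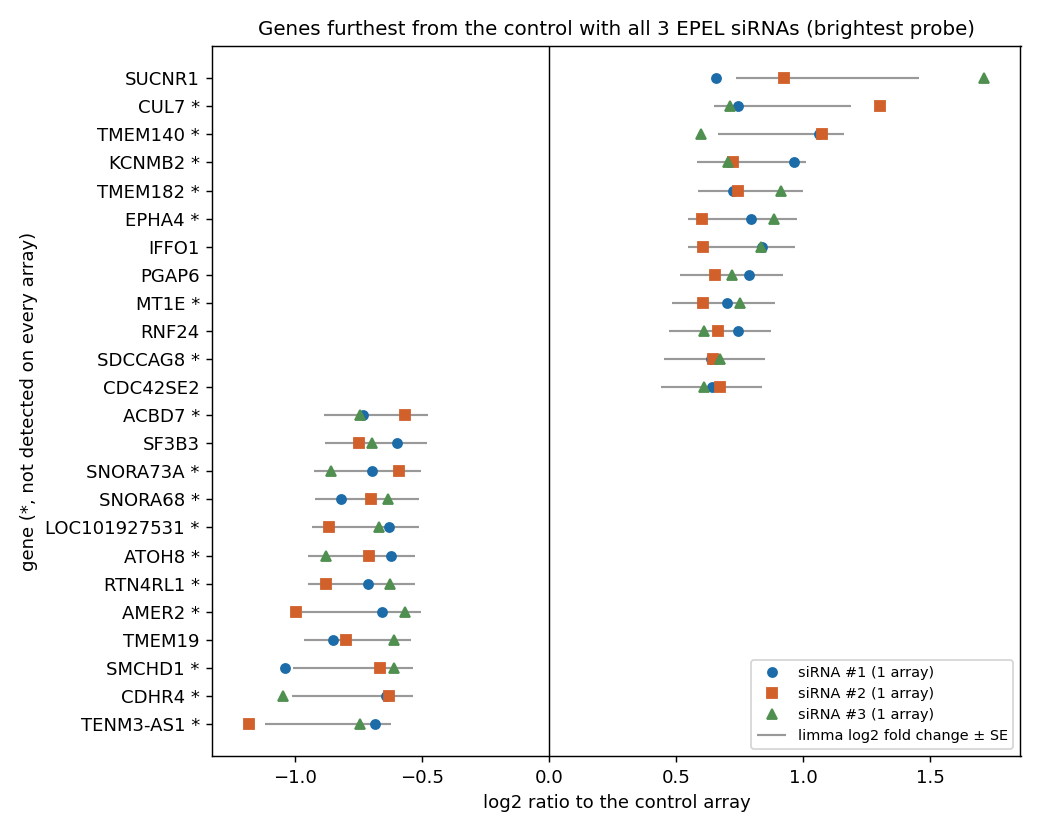
Log2 ratio to the control array (x axis) of the 24 genes with the widest differences shared by all 3 siRNAs by their brightest probe (y axis), with a marker for each siRNA (1 array each) and a line for the limma log2 fold change ± SE. SUCNR1 reaches 1.71 with siRNA 3 against 0.66 with siRNA 1, and 0 of the genes passed an adjusted p of 0.05; genes with an asterisk were not detected on every array, so their plotted ratios are not folds but values near background.

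With each siRNA at least 1.5-fold from the control in the same direction, there were 27 probes higher and 21 lower. Simulated unchanged arrays that share 1 control gave 30.6 higher (95% range 19.98 to 41.03) and 31.0 lower (20.98 to 42). Both observed counts lay within these ranges. The simulation gave every array the spread among the siEPEL arrays, which also holds differences between the siRNAs. It therefore cannot decide whether the shared changes arose by chance. The counts depended on dim probes. They were 8 and 5 among probes detected on all 4 arrays, and 1 and 1 without background correction.

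Genes of the G1/S transition that are known E2F targets lay lower with all 3 siRNAs. The median of the 33 measured genes, out of 40 listed, was 22.3% below the control with siRNA 1, 9.77% with siRNA 2 and 7.07% with siRNA 3, a mean log2 median of -0.21 ± 0.14 (SD, 3 siRNAs). The members furthest from the control were CHAF1A, a histone chaperone of replicating chromatin, at -0.56 ± 0.27 (SE) and E2F2, an activator of S-phase genes, at -0.55 ± 0.21. E2F2 stood at 0.611-fold, 0.729-fold and 0.722-fold the control with siRNAs 1, 2 and 3. Ribonucleotide reductase RRM2 (-0.81, 0.12 and -0.41) and the cyclin gene CCNA2 (-0.65, -0.36 and -0.05) varied between siRNAs. In 19 of the 33 genes all 3 ratios were below 0, against 20.3% of all genes measured. The list's adjusted p was 7.03e-06 (limma camera, preset correlation) and 0.709 with an estimated correlation. Of its members, 0 passed over all probes tested and 0 when adjusted over the list alone.

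The E2F genes themselves lay on both sides of the control. Beside E2F2, the repressor gene E2F7 had a log2 fold change of -0.30 ± 0.21 (SE) and E2F3 of -0.15 ± 0.23. The activator gene E2F1 stood at 0.28 ± 0.21, E2F4 at 0.19 ± 0.21, E2F5 at 0.38 ± 0.21 and E2F6 at 0.27 ± 0.20. E2F8 was not detected on the control array and was detected on 1 siEPEL array, so no fold is given. All 8 missed the threshold.

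DNA replication genes gave the most even shift of the proliferation groups. The 39 measured genes, of 40 listed, had medians 20.2% (siRNA 1), 14.6% (siRNA 2) and 6.52% (siRNA 3) below the control, a mean log2 median of -0.22 ± 0.11 (SD, 3 siRNAs). CDC6, a loader of the replicative helicase, was at -0.45 ± 0.22 (SE), and TOPBP1, which acts in replication initiation and checkpoint signalling, was at -0.43 ± 0.24. The helicase subunits MCM6 and MCM7 lay at -0.30 and -0.46 with siRNA 1, -0.39 and -0.38 with siRNA 2, and -0.24 and -0.14 with siRNA 3. The sliding clamp PCNA lay at -0.03, 0.12 and -0.07. All 3 siRNAs were below the control in 22 of 39 genes. The adjusted p was 1.62e-08 (limma camera, preset correlation), or adjusted p = 0.709 with an estimated correlation. The members past the threshold numbered 0, over all probes and adjusted over the list alone.

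Mitotic genes were lowest with siRNA 1. All 48 listed genes of the G2/M phase were measured, and their median was 23.8% below the control with siRNA 1, 6.77% with siRNA 2 and 8.54% with siRNA 3. The mean log2 median was -0.21 ± 0.16 (SD, 3 siRNAs). ANLN, a scaffold of the cytokinetic ring, had ratios of -0.93, -0.29 and -0.23, and ECT2, a cytokinesis gene, of -0.71, -0.65 and 0.05. The proliferation marker MKI67 lay at -0.81, 0.02 and -0.19. In 28 of 48 genes all 3 ratios were below 0. Camera gave an adjusted p of 1.23e-08, against adjusted p = 0.709 with an estimated correlation. Without siRNA 1 the list's median log2 fold change was -0.11 in place of -0.23. Members past the threshold numbered 0, over all probes and adjusted over the list alone.

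**Figure D2:**
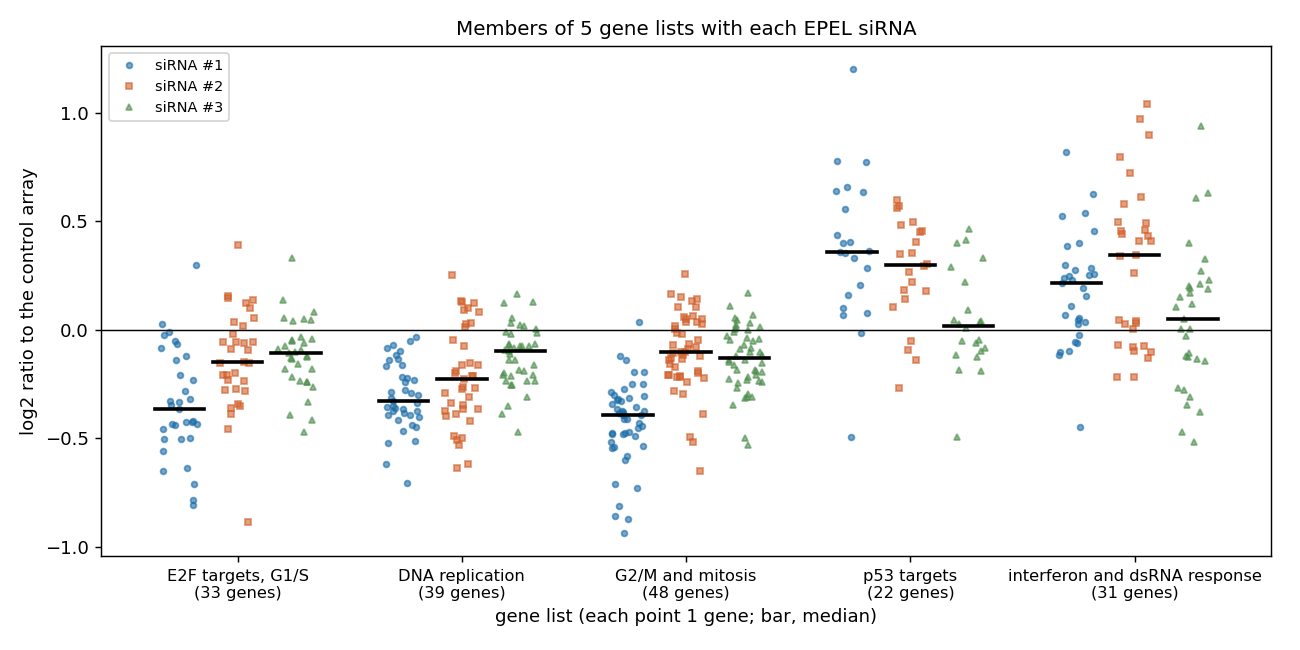
Log2 ratio to the control array (y axis) of every measured member of 5 gene lists (x axis), a point per gene and a bar for the median, with 1 array per siRNA. Medians of the mitotic genes lie at -0.39, -0.10 and -0.13 with siRNAs 1, 2 and 3, and those of the p53 targets at 0.36, 0.30 and 0.02.

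Targets of p53 lay higher with siRNAs 1 and 2 and close to the control with siRNA 3. The 22 measured genes, of 28 listed, had medians 28.4%, 23.0% and 1.21% above the control, a mean log2 median of 0.23 ± 0.18 (SD, 3 siRNAs). SESN1, a stress-induced regulator of growth signalling, was 2.30-fold the control with siRNA 1 and 1.32-fold and 1.38-fold with siRNAs 2 and 3, a log2 fold change of 0.69 ± 0.31 (SE). RRM2B, the p53-induced ribonucleotide reductase subunit, was at 0.51 ± 0.21, and its second probe at 0.26 ± 0.23. The proapoptotic gene BAX lay at 0.78, 0.56 and -0.06. All 3 ratios were above 0 in 8 of 22 genes, against 20.5% of all genes. The adjusted p was 2.60e-05 with limma camera and 0.709 with an estimated correlation, and the median log2 fold change was 0.32 without siRNA 3 in place of 0.18. Of the members, 0 passed over all probes and 0 adjusted over the list alone.

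Other cell cycle and death genes gave no call. CDKN1A, the p21 inhibitor of cyclin-dependent kinases and a p53 target, was 1.56-fold, 1.37-fold and 1.26-fold the control, a log2 fold change of 0.48 ± 0.22 (SE). CCND2 was not detected on the control array and was detected on 1 siEPEL array. The 14 measured CDK inhibitors and G1 cyclins had a median of -0.02, a mean of 0.03 and an upward camera direction, with an adjusted p of 0.842. Without siRNA 3 the median was 0.12. The 18 apoptosis genes had a mean log2 median of 0.11 ± 0.10 (SD, 3 siRNAs) and an adjusted p of 0.0806. Their median log2 fold change of 0.10 was 0.06 without siRNA 2 and 0.04 without the detection filter. BIK, a proapoptotic BH3-only gene, was at 0.40 ± 0.21 and the death receptor TNFRSF10A at 0.37 ± 0.22. The apoptosis list passed without siRNA 3, with an adjusted p of 0.0212 in a range of 0.0212 to 0.788 over all alternatives. Replication-dependent histone genes (12 measured) had a mean log2 median of 0.11 ± 0.10 and an adjusted p of 0.554. Their median log2 fold change of 0.06 was 0.17 without siRNA 3 and -0.01 without siRNA 1. H2AC18 stood at 0.30 ± 0.22 (0.33 ± 0.32 by its second probe) and H4C3 at -0.25 ± 0.20.

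Interferon-induced genes lay highest with siRNA 2. The 31 measured genes, of 38 listed, had medians 15.98% (siRNA 1), 27.1% (siRNA 2) and 3.48% (siRNA 3) above the control, a mean log2 median of 0.20 ± 0.15 (SD, 3 siRNAs). The antiviral GTPase gene MX1 was 1.23-fold, 2.05-fold and 1.55-fold the control, a log2 fold change of 0.66 ± 0.28 (SE). IFIT3, which binds viral RNA complexes, was at least 1.52-fold higher by its brighter probe, while its other probe gave -0.15 ± 0.23. The ubiquitin-like modifier ISG15 lay at 0.05, 0.90 and -0.13. In 14 of 31 genes all 3 ratios were above 0. The adjusted p was 0.000214 with limma camera and 0.709 with an estimated correlation. The median log2 fold change of 0.14 became 0.24 without siRNA 3 and 0.09 without the detection filter. Members past the threshold numbered 0, over all probes and adjusted over the list alone.

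NF-kappaB and cytokine genes gave no call: the 18 measured had a mean log2 median of -0.03 ± 0.04 (SD, 3 siRNAs) and an adjusted p of 0.721. The cytokine gene IL1A, detected on the control array alone, was at least 1.22-fold lower, and PTGS2, the inducible cyclooxygenase gene, was at -0.20 ± 0.20 (SE) and, by its second probe, at -0.01 ± 0.24. Small RNA processing genes (13 measured) had a mean log2 median of 0.04 ± 0.04 and an adjusted p of 0.413. DICER1, which cuts small RNA precursors, was at 0.46 ± 0.22 and, by its second probe, at 0.57 ± 0.26. TNRC6B, a partner of Argonaute proteins, was at 0.41 ± 0.25.

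Hypoxia and glycolysis genes lay slightly below the control, by amounts close to one another. The 28 measured genes, of 32 listed, had medians 6.87%, 4.13% and 7.16% below the control with siRNAs 1, 2 and 3, a mean log2 median of -0.09 ± 0.03 (SD, 3 siRNAs). ALDOC, a glycolytic aldolase, was at 0.550-fold, 0.661-fold and 0.695-fold, a log2 fold change of -0.66 ± 0.22 (SE). MXI1, an antagonist of MYC, was at least 1.15-fold lower. GAPDH lay at 0.14, 0.21 and 0.09. In 12 of 28 genes all 3 ratios were below 0. The list's adjusted p of 0.0117 (limma camera) became 0.709 with an estimated correlation and 0.0580 without siRNA 3. Members past the threshold numbered 0, over all probes and adjusted over the list alone.

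The remaining lists did not pass. NRF2 targets (22 measured) had a mean log2 median of 0.06 ± 0.04 (SD, 3 siRNAs) and an adjusted p of 0.211. The heme-degrading enzyme HMOX1 lay at 0.85, 0.64 and -0.28 and the cystine transporter SLC7A11 at 0.90, 0.43 and 0.05. Unfolded protein and amino acid stress genes (30 measured) stood at 0.02 ± 0.04 with an adjusted p of 0.989, with the secreted glycoprotein gene STC2 at -0.41 ± 0.24 (SE). Sterol and fatty acid synthesis genes (25 measured) stood at -0.02 ± 0.02 with an adjusted p of 0.898. Among them EBP was at -0.33 ± 0.22 and CYP51A1 at 0.32 ± 0.21. MYC and ribosome biogenesis genes (32 measured) stood at 0.04 ± 0.04 with an adjusted p of 0.720. The cap-binding factor EIF4E was at 0.42 ± 0.23 by its brighter probe and -0.27 ± 0.30 by the other, and UTP20 was at least 1.16-fold higher. Matrix and epithelial-mesenchymal transition genes (26 measured) stood at -0.05 ± 0.08 with an adjusted p of 0.639. CCN2 gave -0.34 ± 0.29 by its brighter probe and 0.00 ± 0.32 by the other. Lung epithelial genes (15 measured) stood at -0.03 ± 0.07 with an adjusted p of 0.898, with the tight junction gene CLDN1 at -0.35 ± 0.24. LAMP3 gave 0.44 ± 0.22 and -0.21 ± 0.31 by its 2 probes.

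Markers of other cell types were mostly undetected. Of 28 listed genes for fibroblasts, endothelium, leukocytes and erythroid cells, 5 were measured, with a mean log2 median of 0.20 ± 0.09 (SD, 3 siRNAs) and an adjusted p of 0.0806. Their median log2 fold change of 0.27 was 0.42 without siRNA 1, 0.14 without siRNA 3 and 0.07 without the detection filter. COL1A1 was at least 1.19-fold higher by the siEPEL mean, but it was detected on 2 of the 3 siEPEL arrays and lay at 0.08 with siRNA 3. The lysosomal gene CD68 was at 0.46 ± 0.20 (SE) by its brighter probe and 0.10 ± 0.20 by the other. In each of these 12 lists without a call, 0 members passed over all probes and 0 adjusted over the list alone. Median, mean and camera direction differed in sign for the MYC list (median -0.02, mean 0.02, upward) and the lung list (median 0.02, mean -0.02, downward). Both medians turned without siRNA 1, to 0.03 for the MYC list and -0.05 for the lung list, and the MYC median was also 0.02 without siRNA 2. The lung median was also -0.04 without siRNA 3 and -0.01 with median scaling. The stress list had a mean of 0.00069 with a downward direction and a median of -0.01, which was 0.04 without siRNA 2 and 0.01 with a gene's probes averaged. The per-siRNA medians of the sterol list averaged below 0, while the median and mean of its fold changes were above 0. Its median of 0.02 was -0.04 without siRNA 3, -0.02 with a gene's probes averaged and -0.01 with median scaling. With median scaling the NRF2 median of 0.08 was 0.00, and without a detection filter the matrix median of -0.09 was -0.01. The matrix median was also -0.05 without siRNA 1, -0.05 without siRNA 2 and -0.12 without siRNA 3.

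Of the 18 lists, 4 were lower and 2 higher with camera at a preset correlation of 0.01, and 0 with the correlation estimated per list or with fry. In simulated lists of 30 genes whose residuals correlate at 0.3, the preset test called 42.4% of lists without a shift. Among the called lists the estimated correlation was 0.653 for mitosis, 0.413 for p53 and 0.290 for G1/S. It was 0.165 for DNA replication, 0.108 for interferon and -0.034 for hypoxia, so the simulated rate does not carry over to each list. The estimated-correlation test called 0% of lists with a true shift of -0.22, also when the genes were independent. Under that test the called lists share 1 adjusted p because the Benjamini-Hochberg adjustment tied their values. Hypoxia lost its call although its estimated correlation was below 0. A call lost under that test therefore does not show that correlation between genes produced the preset call.

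**Figure D3:**
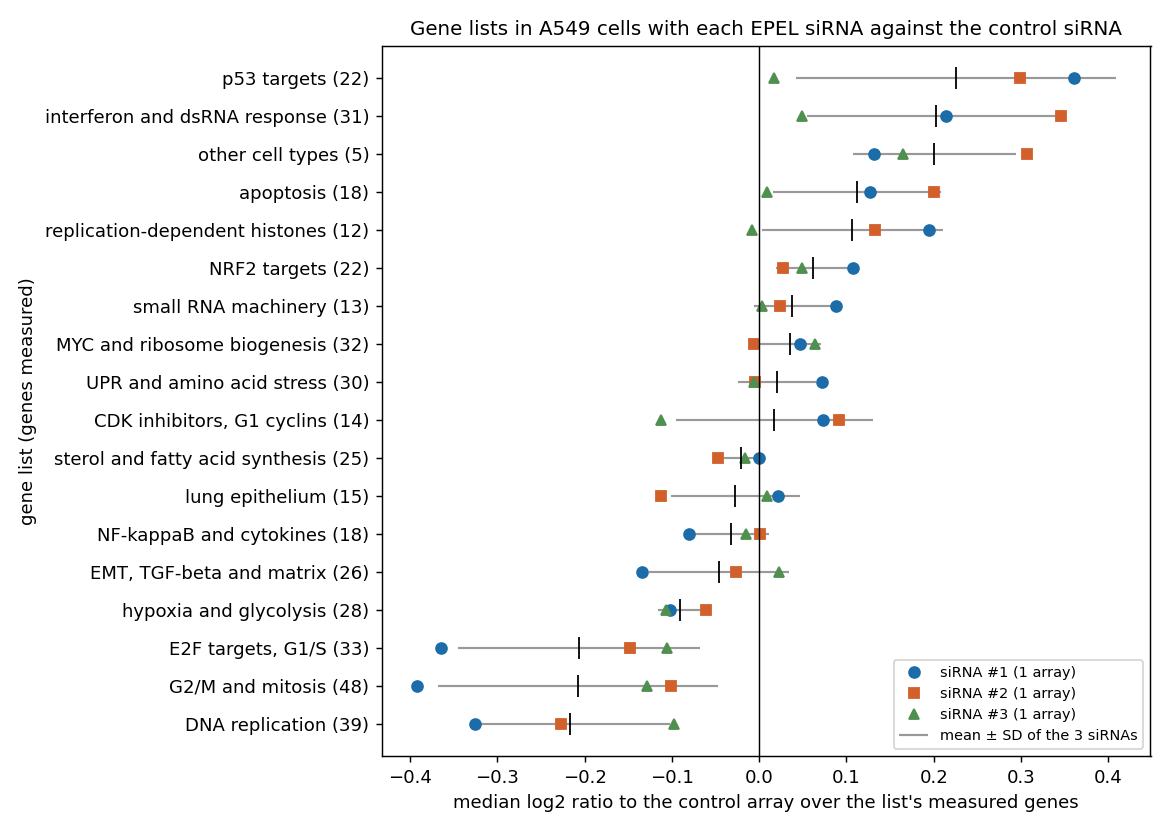
Median log2 ratio to the control array (x axis) of each of the 18 gene lists (y axis, number of measured genes in brackets), with a marker per siRNA (1 array each), a tick at the mean and a line for ± SD of the 3 siRNAs. The 3 proliferation lists lie between -0.39 and -0.10 with every siRNA, and the p53 and interferon lists reach 0.36 and 0.35 but lie at 0.02 and 0.05 with siRNA 3.

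The 3 siRNAs differed from one another more than from the control. The SD of the log2 difference between arrays was 0.244 to 0.302 for the control against each siRNA and 0.310 to 0.350 between siRNAs. At least 1.5-fold from the control lay 985 probes with siRNA 1 (427 higher, 558 lower), 1131 with siRNA 2 (535 and 596) and 501 with siRNA 3 (261 and 240). Of these, 76.3%, 78.2% and 63.3% reached that size with that siRNA alone. At 2-fold the counts were 67, 68 and 24. With 1 array per siRNA, these single ratios have no replicate check.

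Across probes, which are not independent replicates, the log2 ratios of siRNAs 1 and 2 correlated at r = 0.314, those of 1 and 3 at 0.348 and those of 2 and 3 at 0.367. Unchanged arrays that share 1 control gave 0.50 for each pair in simulation. The covariances of 0.0280, 0.0250 and 0.0270 lay below the simulated 0.0413, 0.0412 and 0.0412, differences of -0.0133, -0.0162 and -0.0143. Pairs of siRNAs shared 78, 60 and 71 probes at least 1.5-fold higher, where independent lists would share 12.6, 6.12 and 7.67. They shared 82, 45 and 49 probes lower, where independent lists would share 18.3, 7.36 and 7.86. Unchanged arrays that share 1 control gave means of 79.2 to 80.3 shared probes higher and 80.8 to 81.5 lower, and 0 of the 6 observed counts lay above the simulated 95% range. Counts of 60 higher, 45 lower and 49 lower fell below it, so the simulation gave more agreement than the data. The simulated control had the spread of the siEPEL arrays, which also holds differences between the siRNAs. The comparison therefore cannot decide whether the siRNAs share a response beyond the control. The single control cannot be split.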

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

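All alternatives were chosen before the data were examined. The count of probes past the threshold was 0 in every alternative (limma), and the probes at an unadjusted p under 0.05 numbered between 216 (detected on all 4 arrays) and 1863 (no detection filter). With a gene's probes averaged, 186 genes were at an unadjusted p under 0.05. No paired analysis was possible because the control group has 1 array, which also cannot be left out, and the target has no named probe here to vary. The counts of probes at least 1.5-fold from the control with all 3 siRNAs, 27 higher and 21 lower, depended on dim probes. They became 1 and 1 without background correction, 3 and 1 with an offset of 50, and 8 and 5 among probes detected on all 4 arrays, since these settings shrink or drop dim signals. Without a detection filter, which adds probes, 35 were lower. With the authors' processed values 42 were higher, and the cause was not tested. At 1.3-fold the counts were 174 and 142, at 2-fold 2 and 0, and with 1 siEPEL array left out 60 to 78 and 45 to 82, because fewer arrays had to pass. The mean correlation between siRNAs, 0.343, was 0.314 with fewer probes (detected on all arrays) and 0.400 with more (no filter). The 4 lower and 2 higher lists became 0 and 0 with an estimated correlation (adjusted p = 0.709 for all 6) and with fry (0.788 for 5 and 0.0610 for hypoxia). With camera at the preset correlation, 5 of the 6 passed in every alternative, with adjusted p up to 0.0234, the interferon list without a filter. The hypoxia list ranged from 0.0179 to 0.0580 with 1 array left out and lost its call without siRNA 3. The cause was not tested. Of 627 values of named genes under alternatives, 2 changed sign: IFIT3 (-0.15 among probes detected on all arrays, where another probe stands for it) and CCND2 (-0.12 without a filter). Signal over background limits what can be read from genes near detection.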

Other observations

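The tests in this part were chosen only after the results were seen, and so were its gene groups apart from the proliferation, p53, interferon and histone lists. With 1 array per siRNA, the percentiles below place a group's median among 10000 random lists of the same size and brightness and describe these arrays only. EGR1, an immediate early transcription factor of growth signals, was at 0.286-fold the control with siRNA 1, 0.873-fold with siRNA 2 and 0.479-fold with siRNA 3. FOS, a subunit of the AP-1 factor, was at 0.487-fold, 0.733-fold and 0.547-fold. Over 21 immediate early genes, the median log2 ratio was -0.17 with siRNA 1 (percentile 0.69), 0.10 with siRNA 2 (percentile 92.6) and -0.04 with siRNA 3 (percentile 21.05). The list thus lay inside the central 95% of random lists with siRNAs 2 and 3, although EGR1 and FOS were low with siRNA 3. Genes of glucuronidation and xenobiotic metabolism (15 measured) lay at 0.30 with siRNA 1 (percentile 99.97), 0.02 with siRNA 2 and 0.07 with siRNA 3. Metallothionein genes (7 measured) lay at -0.31, 0.16 and -0.17, although MT1E lay above the control with each siRNA.

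Large single-siRNA differences concerned other genes, taken among those detected on all 4 arrays. With siRNA 1, the zinc finger gene ZMYM2 was at 0.443-fold the control and LMNB1, a nuclear lamina protein that declines in senescent cells, at 0.469-fold, while both lay between 0.914-fold and 1.04-fold with the other siRNAs. With siRNA 2, CNOT7, a deadenylase of the CCR4-NOT complex, was at 0.359-fold, against 0.975-fold and 0.830-fold with siRNAs 1 and 3. The cytokine gene IL11 was at 1.87-fold with siRNA 2 and 0.483-fold with siRNA 1. With siRNA 3, CPS1, the first enzyme of the urea cycle, was at 0.429-fold, against 1.09-fold and 1.00-fold with siRNAs 1 and 2. The probe with the smallest unadjusted p of all, 1 of 2 for the mitochondrial chaperone HSPE1, had log2 ratios of 1.39, 1.70 and 1.16. The brighter HSPE1 probe had ratios of 0.04, 0.05 and 0.00, so the probes disagree and no level is given for the gene. CCDC91 was alike, with 1.02, 1.27 and 1.10 by a dim probe and 0.07, 0.21 and 0.15 by its brighter one.

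The 120 genes of the 3 proliferation lists had a pooled median log2 ratio of -0.369 with siRNA 1 (117 of 120 below the control), -0.150 with siRNA 2 (85 of 120) and -0.114 with siRNA 3 (95 of 120). A trend with brightness is argued against, since the median over the mean of the 3 ratios, -0.222, lay below all 10000 random lists of like brightness. The median difference between siRNA 1 and the mean of the other siRNAs was -0.217; the control array does not enter it, so it is no test of that array, and its chance spread is not known with 1 array per siRNA. The part shared by all siRNAs, down to -0.114, cannot be told apart from a deviation of the single control array, since every ratio uses it. Whether siRNA 1 lowered its target most, which may underlie its -0.369, stays open for want of a named probe here, and a response of proliferation to the loss of EPEL stays open as well.

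The interferon list lay at 0.214 with siRNA 1, 0.346 with siRNA 2 and 0.049 with siRNA 3. The difference between siRNA 3 and the mean of the other siRNAs was -0.178, which is no test of the control array either. A response to particular siRNA molecules may act through sensors of double-stranded RNA. It cannot be told apart from a response to EPEL loss at 0.346, with 1 array per siRNA and no knockdown value used here. The p53 list was also lowest with siRNA 3, at 0.360, 0.299 and 0.017, a difference of -0.309 between siRNA 3 and the others.

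Small nucleolar RNA genes (79 measured), guides of RNA modification, lay at -0.062, -0.329 and -0.127, with 62 of 79 below the control with siRNA 2. With siRNA 3, 52 of 79 were below the control, and the median over the mean of the 3 ratios was -0.209. The group was chosen after its low level was seen, so the difference of -0.206 between siRNA 2 and the others restates the pattern. Other RNAs without a poly(A) tail went both ways with siRNA 2. The histone list stood at 0.133 (percentile 92.26, 5 of 12 genes below the control). A group of 8 small nuclear RNA genes, taken by name, stood at -0.28 (percentile 1.24, 7 of 8 below). With siRNAs 1 and 3 that group stood at 0.19 and -0.43. Poor priming of such RNAs, a loss of short RNAs in 1 preparation and a change in the cells cannot be told apart at -0.329, the level with siRNA 2.

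Each of the 4 arrays was also set against the other 3. The real comparison gave 382 probes at an unadjusted p under 0.05 and the highest other, with siRNA 2 alone, 1681. All 4 of 4 splits gave at least as many as the real one, and 4 splits are too few for a share under 0.05. With siRNA 1 as the lone array there were 1651 probes and with siRNA 3 541.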
